A study of Brachypodium distachyon with 7 samples.

How the data were processed

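Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map 2 histone modifications in seedlings of the grass Brachypodium distachyon, line ABR1. H3K4me3 is a mark commonly found at the start of active genes, and H3K27me3 is a mark of Polycomb-repressed genes. Per the labels' protocols, aerial parts of seedlings were pooled, plants grew at 24 °C in days of 16 h light and 8 h dark, and libraries were made with a TruSeq ChIP kit. V0 plants were taken 17 days after sowing without cold. V30 plants grew for 14 days and then spent 30 days at 4 °C. V30N plants grew for 7 days, spent 30 days at 4 °C and were returned to warmth for 7 days. The series held 7 libraries: 2 of H3K4me3 in V0 and 1 for every other combination of mark and condition. The labels number the H3K4me3 V0 libraries but do not say whether they came from separate plantings, so p-values measure only the spread between these libraries, which may be technical.

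The deposited tables gave 1 signal value per gene and library, in a column whose abbreviated name the file headers do not spell out. The authors' alignment used Bowtie2 2.1.0, per the submitters' processing notes. The genome build, gene annotation, region calling, input correction and normalization of the signal were not given in the sources used here, so the depth behind each value is unknown and no counting interval was computed. Each H3K4me3 table held the same 11752 genes and each H3K27me3 table the same 6554 genes, and no value was 0. The tables identify genes by Bradi locus identifiers. None of these matched the reference gene table used here (assembly Brachypodium_distachyon_v3.0). Gene names were therefore attached only to loci listed by identifier before the data were examined, from published assignments, and other genes are given by identifier, at most 2 per direction and comparison. Lists that needed gene descriptions, such as photosynthesis or ribosomal proteins, were not formed.

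Values were compared as log2(signal + pseudocount). The pseudocount was the 1st percentile of the mark's values, 9.41 for H3K4me3 and 27.3 for H3K27me3, and it understates the change of low genes. Values were used as deposited. Centring each library on its median moved every H3K4me3 difference by 0.12 for V30 against V0, -0.11 for V30N against V0 and -0.23 for V30N against V30. V0 of H3K4me3 was the mean of its libraries on this scale. For H3K4me3, limma 3.58.1 (R 4.3.3; lmFit, eBayes with a variance trend) was fitted to all 4 libraries with 1 coefficient per condition and Benjamini-Hochberg adjustment over all genes. A gene passed at an adjusted p under 0.05. The only residual degree of freedom came from the V0 libraries, so V30 and V30N were assumed to vary as V0 did. The prior on the variance outweighed it completely: each gene's standard error was the value of the trend at that gene's level, whatever the gap between its own V0 libraries. H3K27me3 had 1 library per condition and no test. For both marks, genes were also counted by size, at 2-fold and at 1.5-fold, both on the log2 scale with the pseudocount.

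Gene lists fixed before the data were examined covered flowering time and vernalization (15 loci), cold response (15 loci: CBF and IRI genes), the circadian clock (5 loci) and reference genes (7 loci). For a list with at least 5 measured members, the median log2 difference was placed among those of 10000 random lists of the same size matched on decile of level. That percentile describes these libraries and is not a p-value. Named genes were every measured locus of the flowering list, then the 5 genes with the largest difference in each direction among those past the threshold, at or above the lower quartile of level, and the most different member of any list outside the middle 95% of random lists.

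The limma step was tested on simulated data for V30 against V0 of H3K4me3: of 11752 genes, 200 were changed, with the V0 spread measured on genes free of tied values (described with the libraries). It recovered 83% of 100 genes changed by 1 on the log2 scale and 100% of 100 genes changed by 2, with 13 false calls. The simulated SD per library was 0.197 and tied values were not simulated. With all genes kept, the V0 libraries gave 0.266, and the median SE of V30 against V0 was 0.381. The recovery therefore does not carry over to the counts reported below, which include tied genes. The list step placed a simulated list shifted by -1 at percentile 0, and 0 of 20 unshifted lists fell outside the middle 95%. Alternatives covered the pseudocount, scaling (median centring, quantile normalization), a filter on the 25% of genes with the lowest level, the variance trend, the size threshold and leaving out each V0 library. Leaving out genes with tied values (also from the gene lists, where under 5 members then gave a median and no percentile), and removing the trend of H3K27me3 differences with level by lowess, were added after the data had been seen. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.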

Results

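H3K4me3 and H3K27me3 were profiled in Brachypodium seedlings without cold (V0), at the end of 30 days at 4 °C (V30) and after 7 days back in warmth (V30N). Vernalization is the promotion of flowering by long cold, and the 3 conditions ask which chromatin changes cold brings and which outlast it. V0 plants were 17 days old, whereas V30 and V30N plants had spent 30 days in the cold after 14 and 7 days of growth. Age and growth before cold therefore differ with condition and cannot be told apart from cold and return to warmth. H3K4me3 had 2 V0 libraries and 1 library each of V30 and V30N, with signal for 11752 genes. H3K27me3 had 1 library per condition, with signal for 6554 genes, so its differences have no replicate check. Of these genes, 1872 carried both marks. Median signal per gene was 43.0 and 55.4 in the H3K4me3 V0 libraries 1 and 2, 44.4 in V30 and 53.6 in V30N. For H3K27me3 it was 117 in V0, 114 in V30 and 116 in V30N.

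At V0, the flowering genes differed widely in their marks. FUL2 (Bradi1g59250), a MADS-box gene related to VRN1, had an H3K27me3 signal of 1202, above 99.6% of genes with this mark. VRN1 (Bradi1g08340), the MADS-box promoter of flowering induced by cold in temperate grasses, had 726, above 97.1%. FT1 (Bradi1g48830), a florigen gene, had 565, SOC1 (Bradi1g77020), another MADS-box gene, 360, and the florigen relative FT2 (Bradi2g07070) 337. VRN2L (Bradi3g10010), related to the cereal flowering repressor VRN2, had 178. ELF3 (Bradi2g14290), an evening gene of the circadian clock, was low in H3K27me3 at 73.3 and high in H3K4me3, at 123 ± 0.45 (SD, n = 2), above 99.4% of genes with that mark. For H3K4me3, VRN1 and FT2 had deposited values of 22.3 and 23.2 in the V0 libraries, the same for both genes. Their mean lay above 10.7% of genes with that mark, but such shared values need not reflect a low level.

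Those values recurred. In each H3K4me3 library, many genes shared exactly 1 value: 1139 genes had 22.3 in V0 library 1, 74 had 23.2 in V0 library 2, 1012 had 22.9 in V30 and 208 had 25.4 in V30N. These are called tied values here. At the 1139 genes tied in V0 library 1, the median was 55.3 in V0 library 2, and at the 1012 genes tied in V30 the medians in the V0 libraries were 39.3 and 50.9. In all, 2429 genes were tied in at least 1 library and 9323 in none. H3K27me3 had no such value.

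**Figure D1:**
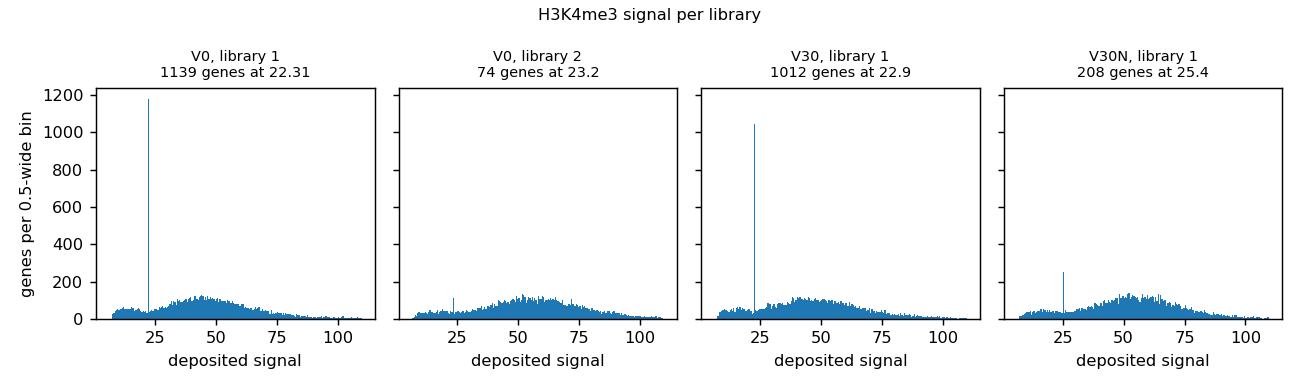
Number of genes (vertical axis, bins 0.5 signal units wide) by deposited H3K4me3 signal (horizontal axis; higher values not shown) in the 4 libraries. The spike in each panel is the tied value, held by 1139, 74, 1012 and 208 genes.

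The H3K4me3 libraries did not group by condition. The V0 libraries differed by a median of 0.24 on the log2 scale, with an SD over genes of 0.38, or 0.28 without tied genes. Across genes free of tied values, which are not independent replicates, Pearson's r was 0.902 between the V0 libraries and 0.960 between V0 library 2 and V30N. The remaining r values lay between 0.880 and 0.910. Low values also differed in how they were spaced. In V0 library 1 and V30, 137 of 1240 and 116 of 1183 values below 20 lay on multiples of a coarse step of 0.655 and 0.627 (4.5 expected by chance in each for a step fixed beforehand), and the values fitted 34 finer steps per coarse step, with a mean cosine of their position within a step of 0.995 and 0.991, where 1 is a perfect fit. In V0 library 2 and V30N, 13 of 894 and 28 of 920 values lay on the best coarse step found (0.948 and 4.21 expected), and no number of finer steps fitted (mean cosine at most 0.078 and 0.0998). In H3K27me3, V30 had a coarse step of 0.653 with 34 finer steps, on which 47.2% of values below 45 lay, whereas V0 and V30N had steps of 0.595 and 0.670 with 48 finer steps, holding 36.1% and 36.6%. Values within 0.0012 of a multiple of the step were counted as lying on it. For H3K27me3, this technical split and the cold treatment of V30 cannot be told apart, while V0 and V30N share the same type of step.

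After 30 days of cold, H3K4me3 signal was 66.0 at VRN1 and 72.9 at VRN2L. VRN1 was at the tied value in both V0 libraries, and VRN2L was at 22.3 (tied) and at 34.2, its own value, from which V30 differed by 0.92. Against the mean of the V0 libraries, the log2 differences were 1.23 (SE 0.46) for VRN1 and 1.15 (SE 0.45) for VRN2L. Of the 8 flowering genes measured, 4 had a tied V0 value: VRN1, VRN2L, FT2 and FUL2. The 2 genes past limma's test adjusted over the list alone, VRN1 and VRN2L (smallest adjusted p = 0.0428), were among them, so these passes do not show a difference between measured values. None of the 8 passed over all genes (limma adjusted p of 0.378 for VRN1 and 0.464 for VRN2L). Over the 4 genes without tied values, 0 passed adjusted over the list alone (limma, smallest adjusted p = 0.713) and the median difference was 0.01. The whole list's median of 0.16, at percentile 98.4 of random lists, includes the tied genes, and it was 0.28 with libraries centred and at percentile 93.2 without V0 library 2. FT2 had 32.3 in V30, with a log2 difference of 0.37 (SE 0.42). SOC1 differed by 0.19, ELF3 by 0.13, FUL2 by 0.06, and the photoreceptor genes PHYB (Bradi1g64360) and PHYC (Bradi1g08400) by -0.10 and -0.15, all less than their SE. Median centring, which added 0.12 to each difference, turned the value for PHYB to 0.01, and FUL2 differed by -0.09 without V0 library 1.

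CBF genes encode activators of cold-responsive genes. Their H3K4me3 in V30 differed from V0 by 0.46 at Bradi4g35580 and 0.43 at Bradi4g35590, with SEs of 0.43 and 0.40. The other measured CBF genes differed by 0.29 (Bradi4g35600), 0.02 (Bradi4g35610) and -0.36 (Bradi4g35650). The median over the 5 measured CBF genes was 0.29, at percentile 99.0 of random lists. It was 0.60 (percentile 99.8) against V0 library 1 alone, which shares V30's value spacing, and -0.11 (percentile 78.2) against library 2 alone. Random lists had a median of -0.25 against library 2 alone. None of the 5 passed limma's test over all genes, and 0 passed adjusted over the list alone. The clock gene TOC1 (Bradi3g48880) went from 51.9 and 48.0 to 65.3, and 0 of the 2 measured clock genes passed adjusted over the list alone. The 6 measured reference genes, used to normalize expression assays, had a median of -0.06, or 0.05 with libraries centred, at percentile 56.8, and 0 passed either adjustment. For GAPDH (Bradi3g14120), a gene of high level, the values were 96.2, 106 and 97.9. UBI4 (Bradi3g04730), close to VRN2L in V0 level, varied more, with 20.6 and 35.0 in the V0 libraries and 18.8 in V30.

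**Figure D2:**
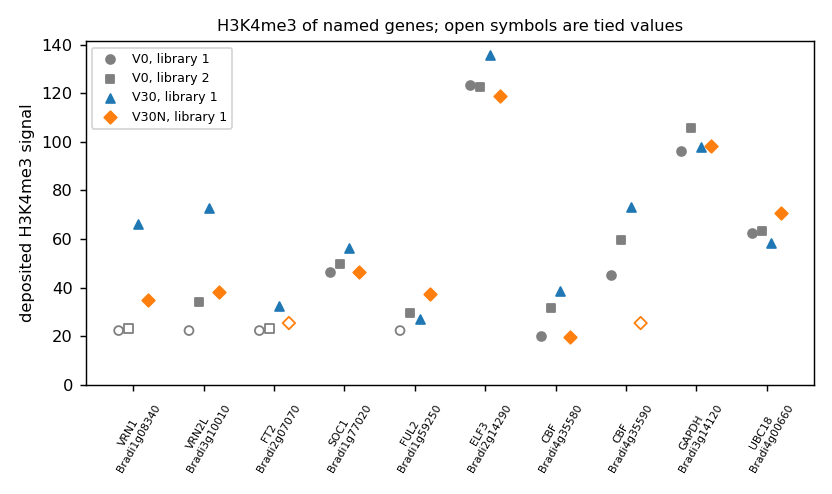
Deposited H3K4me3 signal (vertical axis) of 10 named genes in each of the 4 libraries, with open symbols for tied values. VRN1 and VRN2L have 66.0 and 72.9 in V30 against at most 34.2 in the V0 libraries, where 34.2 is the only value that is not tied. GAPDH, a gene of far higher level, varies between 96.2 and 106.

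Over all 11752 genes, limma called 8 genes with higher and 55 with lower H3K4me3 in V30 than in V0, and 585 had an unadjusted p under 0.05. All of these calls ended with limma under median centring, quantile normalization or a prior without trend, at 860, 703 and 647 genes with an unadjusted p under 0.05. The differences themselves changed little, with a median size of 1.39 as deposited and 1.29 with centring over the 63 genes. All 63 kept their sign in each setting, which says little. Centring shifts each difference by 0.12, and leaving out the trend changes none. The degrees of freedom behind the test went from 11752 to 9.25, 8.42 and 17.8. By size, 27 genes were higher and 252 lower by at least 2-fold, and median centring gave 53 and 151. Genes with tied values made up most of both counts. Of the 55 lower genes, 53 were tied in V30, and of the 279 genes past 2-fold, 264 had a tied value on the lower side. For 16 of these, the other V0 library held a value of their own, and 1 of them, Bradi2g56037, passed 2-fold against it. Without tied genes, limma called 3 genes, all higher, and 13 genes passed 2-fold. With tied genes left out and libraries centred, the limma count was 22 higher and 8 lower. The largest called falls, at Bradi1g04140 (-2.99) and Bradi3g46247 (-1.91), were to the tied value. With centring they were -2.88 (SE 0.77 in place of 0.23) and -1.79 (SE 0.27 in place of 0.30). Bradi1g04140 differed by -1.87 without V0 library 1 and by -4.12 without library 2. Among the largest rises were Bradi2g56037 (2.09), tied in V0 library 2, and Bradi2g42360 (1.84), at 2.21 (SE 0.47 in place of 0.33) and 1.96 (SE 1.21 in place of 0.12) with centring. The latter had 1031 in V0 library 1 and 1133 in V30, against 88.6 in V0 library 2 and 88.7 in V30N. Against V0 library 1 alone, 308 genes were higher and 165 lower by 2-fold, and VRN1 and VRN2L differed by 1.25 and 1.38. Against V0 library 2 alone, the balance turned to 25 higher and 437 lower, or 86 and 164 with libraries centred, and VRN1 and VRN2L differed by 1.21 and 0.92. For comparison, 629 genes were higher and 10 lower by 2-fold in V0 library 2 than in V0 library 1, or 206 and 37 with libraries centred. Most genes in these counts had a tied value. Without tied genes, V30 had 10 higher and 3 lower than V0 library 1, and 11 and 32 than library 2. Between the V0 libraries, 22 and 2 then remained.

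H3K27me3 after cold was lower at genes of both cold-response families. IRI genes encode ice recrystallization inhibition proteins, which limit ice growth in cold-hardy grasses. Signal at Bradi5g27350 was 366 in V0 and 120 in V30, at Bradi5g27340 299 and 97.0, and at Bradi5g27330 239 and 108. The neighbouring Bradi5g27310 (254 and 251) and Bradi5g27320 (284 and 308) differed little. Among CBF genes, Bradi4g35590 had 268 in V0 and 152 in V30, Bradi4g35580 135 and 83.6, and Bradi4g35600 94.6 and 52.9. The lowest one, Bradi4g35640, had 28.0 and 23.5. The median over the 9 measured cold genes was -0.61 on the log2 scale, below all 10000 random lists (percentile 0), with 8 members lower and 1 higher. These genes lie in runs of neighbours, whereas random lists were drawn without regard to position. Differences of adjacent genes correlated (r = 0.281 with the trend with level removed), so the percentile can overstate how unusual the list was. With libraries centred, 7 were lower and 2 higher. The median of the 5 IRI genes was -0.98. V30 was the library with the other type of value step, so no value within 1 type exists for these differences.

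At flowering genes, H3K27me3 was lower in V30 at VRN1 (726 against 474, log2 difference -0.59) and FT2 (337 against 225, -0.53), and higher at SOC1 (360 against 539, 0.55) and FUL2 (1202 against 1518, 0.33). FT1 (565 against 628), VRN2L (178 against 151), ELF3 (73.3 against 67.0) and the CONSTANS-like gene CO1 (Bradi1g43670, log2 difference 0.09) differed by less. The list's median of -0.0025, or 0.03 with libraries centred, lay at percentile 14.2, within the range of random lists. Over all 6554 genes, 4 were higher and 22 lower by at least 2-fold, and 40 and 120 by 1.5-fold (64 and 97 with libraries centred). The largest difference upward was at Bradi4g37860 (32.0 against 148), next to Bradi4g37850, which had the same V30 value. The largest downward was at Bradi4g06740 (204 against 44.4). Differences depended on level: the median was -0.10 in the 25% of genes with the lowest level and 0.15 in the 25% with the highest (Spearman's rho across genes 0.390). Once that trend was removed, the difference at FUL2 was -0.02, at SOC1 0.43 and at VRN1 -0.77.

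After 7 days back in warmth, the lower H3K27me3 at VRN1 and FT2 was still seen. VRN1 had 460 in V30N, with a log2 difference from V0 of -0.63, and FT2 had 209 (-0.62). They ranked 6 and 8 from the lowest among 6554 genes. VRN1 and FT2 were the 2 flowering genes lower by 1.5-fold. The list's median of -0.15 lay at percentile 1.05 of random lists. SOC1 was at 316, FUL2 at 1098, FT1 at 604 and VRN2L at 177. All 4 CBF genes had values above V0, by 0.05 to 0.21, as in Bradi4g35590 with 314. All 5 IRI genes had values below V0, with differences of -0.26 to -0.56 and signal of 163 at Bradi5g27310 and 198 at Bradi5g27340. Whether CBF and IRI genes differed in this respect was not tested. The cold list's median was -0.26, at percentile 0.02. No gene of the 6554 passed 2-fold, and 7 were higher and 16 lower by 1.5-fold, or 7 and 9 with libraries centred. The largest were Bradi3g04370 (45.9 against 91.5) and Bradi2g20150 (147 against 75.4). This comparison rests on the single V0 library that also served for V30, and V0 plants were younger than V30 and V30N plants.

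**Figure D3:**
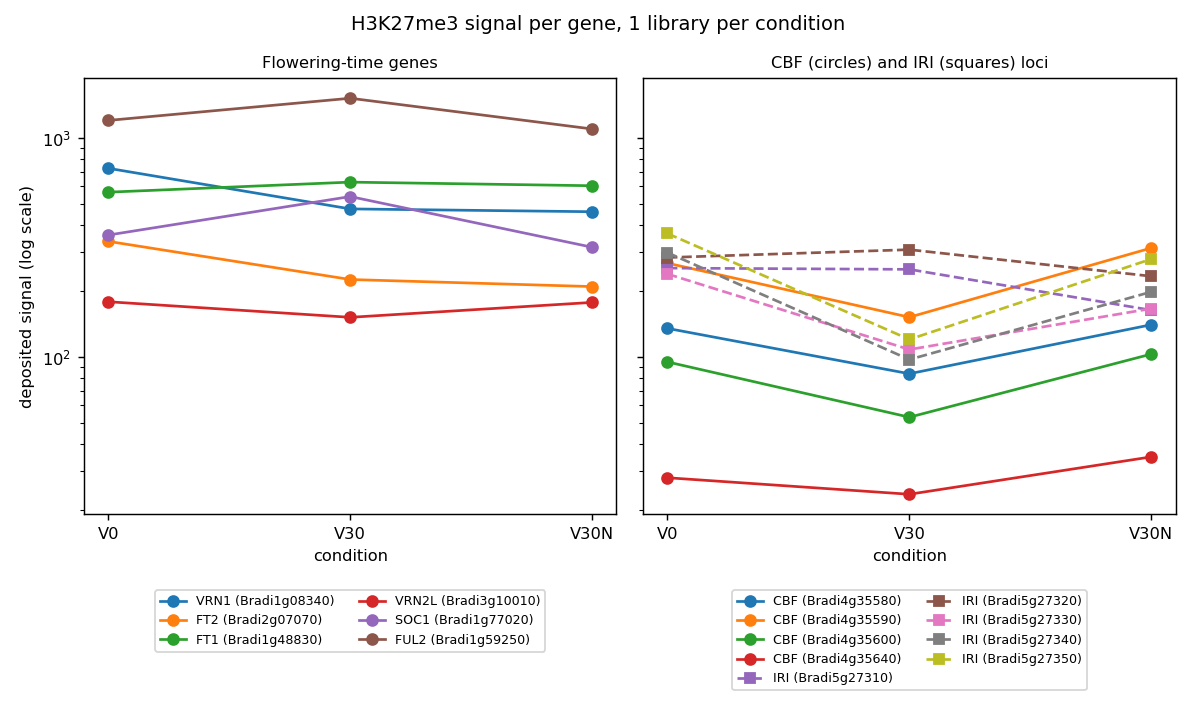
Deposited H3K27me3 signal (vertical log axis) of flowering-time genes (left) and of CBF and IRI genes (right) in V0, V30 and V30N, 1 library each, with lines joining the values of a gene. VRN1 goes from 726 to 474 and 460, and the CBF gene Bradi4g35590 from 268 to 152 and back to 314.

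In V30N, H3K4me3 was 34.8 at VRN1 and 38.0 at VRN2L, with V30N minus V0 log2 differences of 0.46 (SE 0.46) and 0.35 (SE 0.45). For VRN1 the V0 values are the tied ones, and VRN2L differed by 0.12 from V0 library 2, where it had a value of its own, and by 0.58 from library 1. FT2 was at the tied value of 25.4. The flowering list's median of 0.20 lay at percentile 94.6, and it was 0.07 without V0 library 1, 0.36 without library 2, 0.09 with libraries centred and 0.05 over the 4 genes without tied values. The median over CBF genes was -0.25, at percentile 0.13, and it was -0.02 (percentile 7.23) without V0 library 2 and -0.08 over the 4 genes without tied values. The CBF gene Bradi4g35590 was lowest at -0.82 (SE 0.40), at the tied value in V30N. No listed gene passed limma's test, over all genes or adjusted over the list alone. The reference genes had a median of -0.03, or -0.14 with libraries centred, at percentile 14.2. Of all genes, limma called 0 higher and 3 lower, with 132 at an unadjusted p under 0.05: Bradi2g42360 and Bradi1g04140, each with a far higher value in V0 library 1 than in library 2, and a gene tied in V30N. Centring, quantile normalization or a prior without trend ended these calls too, at 121, 127 and 74 genes with an unadjusted p under 0.05 in limma, while the 3 genes kept their sign. By size, 1 gene was higher and 24 lower (1 and 45 with libraries centred), 22 of these 25 with a tied value on the lower side. At 1.5-fold 289 were higher and 88 lower, and centring turned this to 110 and 160. Against V0 library 2 alone, in which no finer steps fitted either, 9 were higher and 34 lower, and VRN1 differed by 0.44. Against V0 library 1 alone, 552 were higher and 27 lower, or 172 and 70 with libraries centred. Without tied genes, 0 were higher and 0 lower against V0 library 2, and 9 and 2 against library 1.

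Between V30 and V30N, H3K27me3 was higher in V30N at most genes of the cold list. Its median was 0.59, above all 10000 random lists (percentile 100), with 7 members higher and 2 lower. The same single V30 library gave the lower values against V0, and it has the other type of value step. This is therefore not separate evidence of a return. Bradi5g27350 went from 120 to 279, Bradi4g35590 from 152 to 314 and Bradi4g35600 from 52.9 to 103. The exceptions were Bradi5g27310 (251 to 163) and Bradi5g27320 (308 to 233). SOC1 went from 539 to 316 (-0.72), FUL2 from 1518 to 1098 (-0.46), while VRN1 (-0.04) and FT2 (-0.10) differed little. Part of this went with level: once the trend with level was removed, the difference at FUL2 was -0.08, at SOC1 -0.62, at VRN1 0.13 and at FT2 -0.06. The flowering list's median was -0.07, at percentile 57.6, and turned to 0.04 with the trend removed. Over all genes, 8 were higher and 4 lower by 2-fold, and 76 and 62 by 1.5-fold, which centring turned to 64 and 75. Bradi4g06740 was highest (44.4 to 165) and Bradi4g37850 lowest (148 to 34.2).

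For H3K4me3, VRN1 went from 66.0 in V30 to 34.8 in V30N (-0.77, SE 0.53) and VRN2L from 72.9 to 38.0 (-0.80, SE 0.52), and neither passed limma's test by either adjustment. V30 and V30N differ in value spacing, so no value within 1 type exists here either. Median centring moved each H3K4me3 difference between them by -0.23. The flowering list's median of -0.20 lay at percentile 0.2, and it was -0.43 with libraries centred, -0.18 (percentile 0.75) without FT2, which is tied in V30N, and 0.06 over the 4 genes without a tied value in any library. The CBF gene Bradi4g35590 had 73.3 in V30 and the tied value of 25.4 in V30N (-1.25, SE 0.47). It passed adjusted over the list alone (limma adjusted p = 0.0374) and not over all genes (limma adjusted p = 0.473), but with a tied value this pass does not show a difference between measured values. Over the other 4 CBF genes, 0 passed adjusted over the list alone (limma, smallest adjusted p = 0.304). The CBF median was 0.03, at percentile 17.2, and turned to -0.19 with libraries centred. The reference genes had a median of -0.02, or -0.25 with libraries centred, at percentile 10.6. limma called 28 genes higher and 6 lower in V30N, with 572 at an unadjusted p under 0.05, and all 28 higher genes were tied in V30, among them Bradi3g21620 (1.91) and Bradi3g28760 (1.78). Without tied genes limma called 0 higher and 2 lower, and with centring added the balance turned to 2 higher and 28 lower. With all genes kept, centring, quantile normalization or a prior without trend ended every limma call, at 823, 743 and 666 genes with an unadjusted p under 0.05, while the 34 genes kept their sign. By size, 371 were higher and 49 lower, or 135 and 119 with libraries centred. Of these 420 genes, 388 had a tied value on the lower side, and without tied genes 27 passed 2-fold.

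Genes that differed in V30 were followed into V30N. For H3K27me3, no gene at all passed 2-fold in V30N against V0, so the count kept at 2-fold says nothing about the 26 genes past it in V30. Of these, 22 had the same sign in V30N, and the 22 that were lower in V30 had a median of -0.23 in V30N. At 1.5-fold, 120 genes were lower in V30. Of these, 2 were still lower by 1.5-fold in V30N, and 44 were higher in V30N than in V30 by that amount. Of the 40 genes higher in V30, 1 was still higher and 16 were lower in V30N than in V30. Because both sets were chosen on the single V30 library, noise in it alone would move some genes back. These counts cannot separate that from recovery. The 2 lower genes kept were VRN1 and Bradi1g16000, the latter named after its values were seen. With libraries centred, 0 of 97 lower genes were kept, and VRN1, at -0.55 in V30, then fell short of 1.5-fold there, as FT2 did at -0.53 without centring. Across genes, the differences of V30 and V30N from V0 correlated with r = 0.407. Both use the same V0 library, and simulated libraries without any effect gave 0.489, with noise borrowed from H3K4me3. The covariance was 0.0188 against 0.0368 simulated, so the borrowed noise exceeds the observed spread and gives no estimate of a shared effect. For H3K4me3, the share kept depended on the V0 library: 1 of 279 genes at 2-fold (0.358%), but 1.30% without V0 library 1 and 51.8% without library 2. The last share rests almost wholly on genes with tied values, and 244 of its 245 kept genes were higher than V0 library 1. Without tied genes, 10 genes in V30 and 9 in V30N were higher than that library by 2-fold. At 1.5-fold, 71 of 257 higher genes and 5 of 893 lower genes were kept. The correlation was 0.203 against 0.345 simulated, with covariances of 0.0168 and 0.0202. The simulated noise was measured on genes without tied values, while the observed values include tied genes, so these are not like for like. Without tied genes the correlation was 0.051 against 0.341 simulated, with covariances of 0.0023 and 0.0196. With V0 library 1 used for V30 and library 2 for V30N, r was -0.024, and -0.25 the other way round.

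**Figure D4:**
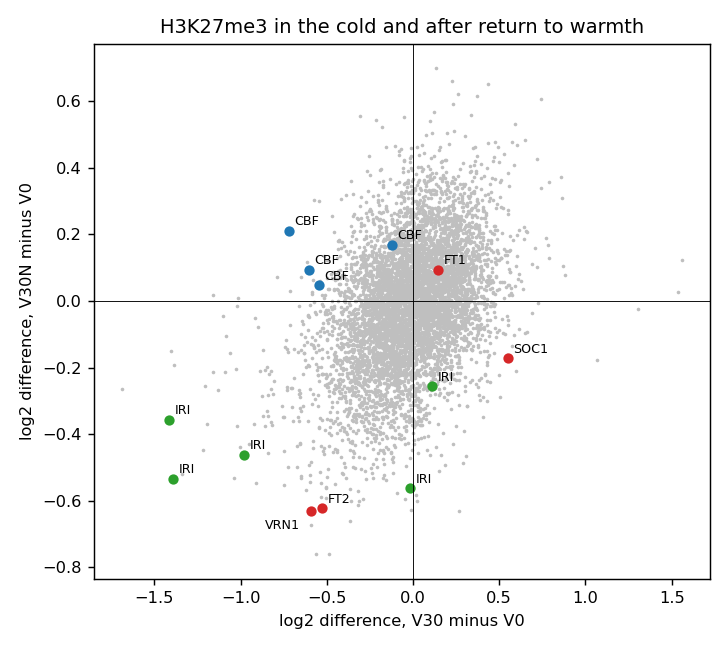
log2 difference of H3K27me3 in V30 against V0 (horizontal axis) and in V30N against V0 (vertical axis) for 6554 genes (grey) and named genes (CBF blue, IRI green, flowering genes red). VRN1 lies at -0.59 and -0.63, and the CBF genes lie at 0.05 to 0.21 on the vertical axis.

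The marks overlapped at 1872 genes, which is 15.9% of the H3K4me3 genes and 28.6% of the H3K27me3 genes. The list of all annotated genes was not used here, so the overlap was not tested. At these genes, V0 levels of the marks correlated with r = -0.164 (Spearman's rho -0.125), across genes that are not independent replicates. Differences between V30 and V0 correlated with r = -0.070 (rho -0.043), those between V30N and V0 with r = 0.032 (rho 0.041) and those between V30N and V30 with r = -0.034 (rho -0.027). At 1.5-fold, 44 of the 1872 genes had more H3K4me3 and 64 had less H3K27me3 in V30 than in V0, and 6 genes had both, where independence would give 1.5. The count was 3 (1.09 expected) without V0 library 1, 13 (5.33 expected) without library 2, and 1 (0.381 expected) without tied genes. VRN1 was one of the 6. With libraries centred the count was 8 (1.96 expected), and VRN1 was not among them, since its H3K27me3 difference of -0.59 was then -0.55. Another of the 6 was Bradi1g76030, with differences of 1.51 and -0.84 and no tied value. The other 4 had a tied value in at least 1 H3K4me3 library, as VRN1 did. The reverse combination was found at 1 gene. Both marks were lower at 4 genes and higher at 0, and without V0 library 1 both were lower at 11.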

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

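Alternatives were chosen before the data were examined, except leaving out tied genes (in any library, in the libraries compared, or with centring) and removing the H3K27me3 trend with level, which were chosen after seeing the data. Of 140 values of named genes with a difference of at least 1.5-fold, 139 kept their sign, while 65 moved by more than 0.20, the SD per library of the H3K4me3 V0 libraries without tied genes, which served for both marks. The exception was H3K4me3 of Bradi2g42360 in V30N against V0, at -3.41 without V0 library 2 and 0.0024 without library 1. A kept sign says little under centring, which shifts differences by at most 0.23 on the log2 scale, less than 1.5-fold. Nor can another pseudocount turn a difference between single libraries. The cold-list medians of H3K27me3 kept their sign and stayed outside the middle 95% of random lists under centring and trend removal. Depth is unknown, and with 1 library per condition no alternative replaces a replicate. No paired analysis was possible because only the H3K4me3 V0 group carries a second numbered library. Tests without a V0 library were not run, since no residual degree of freedom remains.

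For the limma counts of V30 against V0, V30N against V0 and V30N against V30 (63, 3 and 34), a pseudocount 10 times larger gave 15, 1 and 6. Median centring, quantile normalization and a prior without trend each gave 0, 0 and 0. At unadjusted p under 0.05 limma then had 860, 121 and 823 genes with centring, 703, 127 and 743 with quantile normalization, and 647, 74 and 666 without the trend. Without tied genes the first and last counts were 3 and 2, and with centring added the 3 counts were 30 (22 higher, 8 lower), 1 and 30 (2 higher, 28 lower), the last turning the balance of 28 higher and 6 lower. Under centring, quantile normalization and no trend the degrees of freedom behind the test were 9.25, 8.42 and 17.8 in place of 11752, so a gene's own V0 gap counted and p-values were larger for a like ratio of fold to SE. With tied genes left out fewer genes were tested. That the called genes kept their sign says little in any of the 3 comparisons, since centring shifts differences by at most 0.23. No other cause was tested.

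By size, the H3K4me3 counts (279, 25 and 420) became 3, 2 and 3 with the larger pseudocount and 540, 77 and 807 with 0.1 of it. At 1.5-fold they were 1150, 377 and 1655, and at 4-fold 2, 0 and 3. Quantile normalization gave 156 for the first and 228 for the last, and centring 46 for the second and 254 for the last. Without tied genes they were 13, 2 and 27. Leaving out a V0 library gave 462 to 473 for V30, but with opposite balance (25 higher and 437 lower without library 1, 308 and 165 without library 2), and 43 to 579 for V30N. With tied genes left out as well, V30 had 11 higher and 32 lower without library 1, and 10 and 3 without library 2. V30N then had 0 and 0 without library 1, and 9 and 2 without library 2. The H3K27me3 counts (26, 0 and 12) were 0 for V30 against V0 and for V30N against V30 with the larger pseudocount and at 4-fold, and 62 and 29 with the smaller one. At 1.5-fold they were 160, 23 and 138. The size threshold and pseudocount act by construction, and the other causes were not tested.

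H3K4me3 persistence (0.358%) was 6.61% at 1.5-fold, 0% without tied genes, 0% with V0 library 1 used for V30 and library 2 for V30N, and 1.30% to 51.8% with a V0 library left out. The 51.8% rests almost wholly on genes with tied values. Of its 245 kept genes, 244 were higher than V0 library 1. Without tied genes, only 10 genes in V30 and 9 in V30N were higher than that library by 2-fold. Its r of 0.203 turned to -0.024 and -0.25 with V0 split. The V0 spread was 0.28 without tied genes. With the 25% lowest levels left out, the correlations between marks were -0.098 for V0 levels, -0.124 for V30 against V0, -0.031 for V30N against V0 (reversed) and -0.085 for V30N against V30. Leaving out a V0 library took the H3K4me3 cold-list median in V30 from -0.11 to 0.60 (reversed without library 1), that in V30N from -0.37 to -0.019, and the flowering median in V30 from 0.14 to 0.22. The reversed cold-list median lay at percentile 78.2, and random lists there had a median of -0.25. Other causes were not tested.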

Other observations

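The tests in this part were all chosen after the results they measure had been seen. H3K27me3 differences were shared between neighbouring genes. With the trend with level removed, V30 minus V0 correlated with r = 0.281 across 6549 pairs of genes adjacent on a chromosome in the list of H3K27me3 genes, and the permutation p of 0.001 was the smallest that 1000 permutations can give. Among them, 38 pairs held an identical value in some library, as Bradi4g37850 and Bradi4g37860 did, and without these r was 0.271. At 2 places apart r was 0.089, at 5 places 0.046 and at 50 places 0.020. For V30N minus V0, r was 0.190 for adjacent genes and 0.0032 at 5 places. By locus number, the CBF genes and the IRI genes each lie in a run of neighbours, so their members are not independent observations. Random lists were drawn without regard to position, so the H3K27me3 percentiles of the cold list can overstate how unusual it was.

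The IRI run was uneven. Bradi5g27330, Bradi5g27340 and Bradi5g27350 differed by -0.98 to -1.42 in V30 against V0, while Bradi5g27310 and Bradi5g27320 differed by -0.02 and 0.11 then and by -0.56 and -0.26 in V30N against V0. In both comparisons between V30 and another condition, the 3 CBF genes with appreciable H3K27me3 moved by similar amounts, -0.55 to -0.72 against V0 and 0.59 to 0.93 in V30N against V30.

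Lower H3K27me3 at CBF and IRI genes in V30 was weighed against technical explanations. A dependence of V30 differences on signal level is argued against, because the cold-list median was -0.54 once that trend was removed, still below all random lists. A batch shared by V0 and V30N could contribute: their low values have the same type of step, V30 has another, and the median absolute difference of the list was 0.26 between V0 and V30N against 0.61 between V30 and V0. That is also what a reversible effect of cold would give, so batch and cold cannot be told apart for V30 at these genes. V30N has the same type of step as V0, and there all 5 IRI genes lay below V0 (median -0.46) and all 4 CBF genes above it. The lower H3K27me3 of VRN1 and FT2 in V30N lies between libraries of the same type too. For these differences in V30N, a deviation of the single V0 library stays open. So does plant age, since V0 plants were 17 days old and V30N plants were older.

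H3K4me3 V0 library 2 was closer to V30N than to V0 library 1. Lower precision of V0 library 1 and V30 alone is argued against. Given the other correlations, it would put their own r at 0.834 by the third pairing of the libraries. That r was 0.910, higher by 0.0757 (bootstrap over genes 0.0679 to 0.0859). The expected value is divided by the 0.960 between V0 library 2 and V30N, which is part of the pattern. Processing in 2 batches, with V0 library 1 and V30 in one, would go with the value steps. The r of V0 library 1 with V30 exceeded the value from the pairing by condition by 0.0793 (0.0718 to 0.0889). That value has the same divisor, and the intervals cover genes and not libraries. The r of V0 library 1 was 0.910 with V30 and 0.910 with V30N. The excess is therefore no separate sign that V0 library 1 and V30 share a batch. A chromatin state shared by V0 and V30N and lost in the cold would be present in both V0 libraries. Alone, it would not put V0 library 2 closer to V30N than to V0 library 1. Whether such a state adds to the pattern stays open. The r of V0 library 1 with V30N minus that with V30 was -3.34e-05 (-0.0065 to 0.0052), which does not decide it.

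Tied H3K4me3 values may have been filled in by the authors where a library gave a gene no value of its own. The 1139 genes tied in V0 library 1 had a median of 55.3 in V0 library 2, as all genes did (55.4), whereas 355 genes with a value of their own within 10% of the tied value had 27.9 there (25th to 75th percentile 22.4 to 34.1). Loss of H3K4me3 in the cold as a source of the tied values in V30 stays open, since V30 held fewer tied genes than V0 library 1 (a difference of -127) but 938 more than V0 library 2. A list restricted to genes with a value of their own in at least 3 of the 4 libraries could explain why 3 genes were tied in 2 or more libraries where independence would give 146. Those 3 genes were VRN1, FT2 and Bradi1g07457, singled out after their values were seen, and why they differ was not tested.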
